A study of Homo sapiens with 8 samples.

How the data were processed

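Total RNA of MIAPaCa-2 cells was isolated with a column kit, amplified and labelled with Cy3, per the labels' protocols. The 8 arrays were scanned and quantified with Agilent Feature Extraction, per the file headers, which also name hg18 as the build of the probe coordinates. The deposited scanner files hold intensity values per spot: the processed signal, background-subtracted and detrended by Feature Extraction per the file headers, and the mean signal and local background from which it was made. No normalization between arrays is recorded in them. The authors' deposited value table holds log2 values of 6614 probes. Set against the scanner values, its columns equal log2 of the background-subtracted intensity, floored at 10, plus 1 constant per array, which matched within 0.01 on the log2 scale for at least 99.97% of the values compared on each array. How its probes were chosen and why the constants differ between arrays is not given in the sources used here, and its column medians were 7.30, 6.98, 7.85 and 7.64 for the unirradiated arrays of numbers 1, 2, 6 and 9, and 7.15, 6.37, 7.96 and 7.39 for the irradiated ones.

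Samples were grouped by their titles into 4 arrays without re-irradiation (0 Gy) and 4 arrays after 8 Gy of protons. No 2 files held identical values, and the correlation of array pairs across genes was at most 0.993. Each array has 45015 features. Control spots and spots marked as outliers were left out, and spots of a probe were averaged, which gave 41000 probes, 40911 of them with a value on all arrays. No probe was saturated and no quality metric of the headers was out of range. Log2 of the processed signal minus the array's 75th percentile was used. Probes well above background on at least 4 of the 8 arrays were kept (23875 probes), and per gene the probe with the highest mean over the arrays (17622 genes). Gene names came from the probe's accession through a RefSeq gene table of assembly GRCh38.p14, used for names only (23680 probes), from a current symbol in the file (2802), from an older symbol (1128) or from the file's own name (13390).

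The comparison of doses was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) over the 8 arrays, with Benjamini-Hochberg adjustment and a threshold of 0.05. The number of the titles was fitted as a block in an alternative. Deviations of same-numbered samples from their group means correlated across genes at 0.75, 0.71, 0.92 and 0.64 for numbers 1, 2, 6 and 9. The highest correlation of the unirradiated array with an irradiated array of another number was lower in each case (0.43, 0.19, -0.44 and 0.36). The numbers were therefore taken to pair the samples. Each number is also 1 slide, so the slide block is the same fit. The difference between numbers was tested with a moderated F in a fit of number and dose. Gene lists were tested with camera at its preset correlation of 0.01, with an estimated correlation, and with fry. The error of a change is the SD of the 4 same-number differences. Where no probe of a gene was well above background on any array of a group, the change is given as at least N-fold, from the mean of the brighter group against the mean of, per array, the higher of the lowest signal well above background and the probe's own signal.

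The 21 gene lists, the tests, the alternatives and the rule for naming genes were fixed before the data were examined. The rule named the 12 largest rises and falls past the threshold with a gene symbol and the same sign in all 4 numbers, or, with fewer than 5 calls in a direction, the 10 largest moderated t without calling them changed; up to 4 members per list with the lowest p; the 8 genes with the largest F between numbers; and 3 genes fixed by name, among them CDKN1A and MDM2. Some genes that this rule names are not reported here. The alternatives were normexp background correction (offset 50), quantile normalization, median scaling, no filter or a filter on all 8 arrays, the mean of a gene's probes, every probe on its own, a trended and robust spread, the number (or slide) and the scan day as blocks, the deposited value table, and each array left out.

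On simulated arrays with the real means, number differences and residual spread of 17622 genes and 200 changed genes, the fit of doses recovered 16% of 2-fold and 77% of 4-fold changes without the block and 83% and 98% with it, with 0 and 9 false calls. On arrays simulated without other differences between numbers, the F test of numbers recovered 87.5% of 4-fold differences. Noise was drawn independently for each gene, so these rates do not cover errors that genes of an array share. Dim signal limits what can be measured: a fall to background appears only as a bound.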

Results

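The series measured gene expression in MIAPaCa-2 cells, an established line from a human pancreatic carcinoma. The cells had been treated with x-rays and expanded, and the expanded cells were then given 8 Gy of protons or were not irradiated again. RNA was hybridised to 8 Agilent 1-colour arrays, 4 per group. The design text has RNA taken after 4 hours, the titles give that time for the irradiated samples alone, and whether the unirradiated samples were handled in parallel is not stated. The titles give both groups the numbers 1, 2, 6 and 9. What a number stands for is not given in the labels. Unpaired p-values thus measure the spread between these 8 samples. Paired p-values and those of the F test between numbers measure the spread left after number and dose. Either spread may in part be technical. Levels are log2 signals relative to each array's 75th percentile, and the number of arrays limits the precision of every value.

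Between 54.4% and 64.4% of the probes were well above background on an array. The mean was 59.4% ± 0.961 (SD, n = 4) without re-irradiation and 57.6% ± 4.59 (SD, n = 4) after protons. The 75th percentile of the processed signal ranged from 399 on the irradiated array of number 2 to 1000 on the irradiated array of number 6. In numbers 1, 2 and 9 the irradiated array was the dimmer of its pair, and in number 6 it was the brighter one. Each number was hybridised on a slide of its own. All 4 unirradiated samples occupied position 1 of their slide and all 4 irradiated samples position 3, so position and dose cannot be told apart by design. In genes with probes at different places along the transcript, the 3′ probe gained on the 5′ probe on the irradiated array of number 2, by a median of 0.35 on the log2 scale over 3880 genes relative to its partner, against 0.012, 0.035 and 0.14 in numbers 1, 6 and 9.

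The first comparison asks which genes differ 4 hours after 8 Gy of protons. Of 31 measured immediate early genes, which code for transcription factors and regulators that cells switch on within minutes of a stimulus, 8 were lower in the irradiated cells, and 24 in a fit that pairs the samples by number. The set test camera had an adjusted p = 0.0867 with an estimated correlation for this list, or 0.313 with pairs. The rotation test fry, which asks whether members change but not whether they change more than other genes, had a paired adjusted p = 0.0177. FOS, a subunit of the AP-1 transcription factor, was 31.3-fold lower (log2 change -4.97 ± 0.79, SD of the 4 pairs). NR4A1, an orphan nuclear receptor, was 21-fold lower (-4.39 ± 0.32) and NR4A3 13.7-fold (-3.77 ± 0.70). NR4A2 had a measured log2 change of -4.07 ± 0.39, but only 1 of its 4 irradiated arrays was above background, so no fold is given. The stress-induced transcription factor ATF3 was 15.1-fold lower (-3.92 ± 1.05) and FOSB 12.2-fold lower (-3.61 ± 0.40). PPP1R15A, a phosphatase subunit that ends the integrated stress response, was 8.71-fold lower, and ZFP36, which speeds the decay of cytokine mRNAs, 8.68-fold lower.

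In all, 28 of 17622 genes passed an adjusted p of 0.05 in limma's moderated test, 28 of them lower and 0 higher after protons. By measured values all were at least 2-fold lower, though some were at background on irradiated arrays. Of the 28, 19 carried a gene symbol under the naming rule. At an unadjusted p under 0.05, 647 genes were lower and 265 higher, and in the paired fit described below 1917 were lower and 3053 higher. The adjusted p was 0.00357 for NR4A1, 0.00886 for FOS, NR4A2 and ATF3, 0.034 for NR4A3, 0.0205 for FOSB, 0.0196 for PPP1R15A and 0.027 for ZFP36. The 12 largest falls with a gene symbol also took in 4 genes whose probes were not well above background on any irradiated array, so that only a lower bound of the fall was measured. TEX14 was at least 6.37-fold lower (adjusted p = 0.00886), ASB2 at least 3.67-fold (0.035), the cytokine gene TNF at least 3.26-fold (0.033) and the smooth muscle calponin gene CNN1 at least 2.54-fold (0.0039). Normexp background correction ended the calls of NR4A2 (log2 change -0.99, adjusted p = 0.8), NR4A3 (-3.11, 0.111), TEX14 (-0.88, 0.8), ASB2 (-0.38, 0.953), TNF (-0.26, 0.991) and CNN1 (0.042, 0.995). That fit was off on the irradiated array of number 6, where 6 spots had a very high local background. With these repaired NR4A3 passed (-3.35, adjusted p = 0.0351), while NR4A2 (-1.68, 0.156), TEX14 (-1.56, 0.156), ASB2 (-1.05, 0.774), CNN1 (-0.72, 0.96) and TNF (adjusted p = 0.96) did not. With no filter on dim probes the adjusted p was 0.0571 for NR4A3 and TNF, 0.0612 for ASB2 and 0.0514 for ZFP36, and under quantile normalization it was 0.0551 for ASB2. Probes of 1 gene did not always move together: another NR4A1 probe above background changed by -0.03 on the log2 scale (mean of its probes -2.21), whereas another ATF3 probe changed by -4.62. The FOS probe lies on chromosome 14 at 74817967-74818026, the NR4A1 probe on chromosome 12 at 50739445-50739504 and the ATF3 probe on chromosome 1 at 210860479-210860538, all in the hg18 coordinates of the array files and all named by the RefSeq transcript they were designed to.

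The numbers paired the samples, and the paired fit, with the number as a block, called 839 genes, of which 651 were lower and 188 higher. All 28 genes above were among them. With the block, normexp left 7 genes (4 of the 28), no filter on dim probes 68 (19 of the 28), so most of the 839 calls ended in these settings, and normexp with repaired backgrounds gave 2039 (all 28). By measured values, 289 of these 839 genes were at least 2-fold lower and 11 at least 2-fold higher, and 527 carried a gene symbol under the naming rule. The paired split between directions moved with the scaling, from 22.4% higher genes to 55.7% when arrays were scaled to their median. Without the pair of number 2, which holds the largest 3′ shift, the paired fit called 424 genes, 394 lower and 30 higher, with 27 of the 28 among them, and the unpaired fit called 1. Without the pair of number 9, where the shift was 0.14, the paired fit called 183 genes, 177 lower and 6 higher, again with 27 of the 28. Single arrays decided much of the unpaired count, which was 4 without the unirradiated array of number 2 or 9, 3 and 9 without the irradiated array of number 9 or 1, 18 without the unirradiated array of number 1 and 63 without that of number 6.

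**Figure D1:**
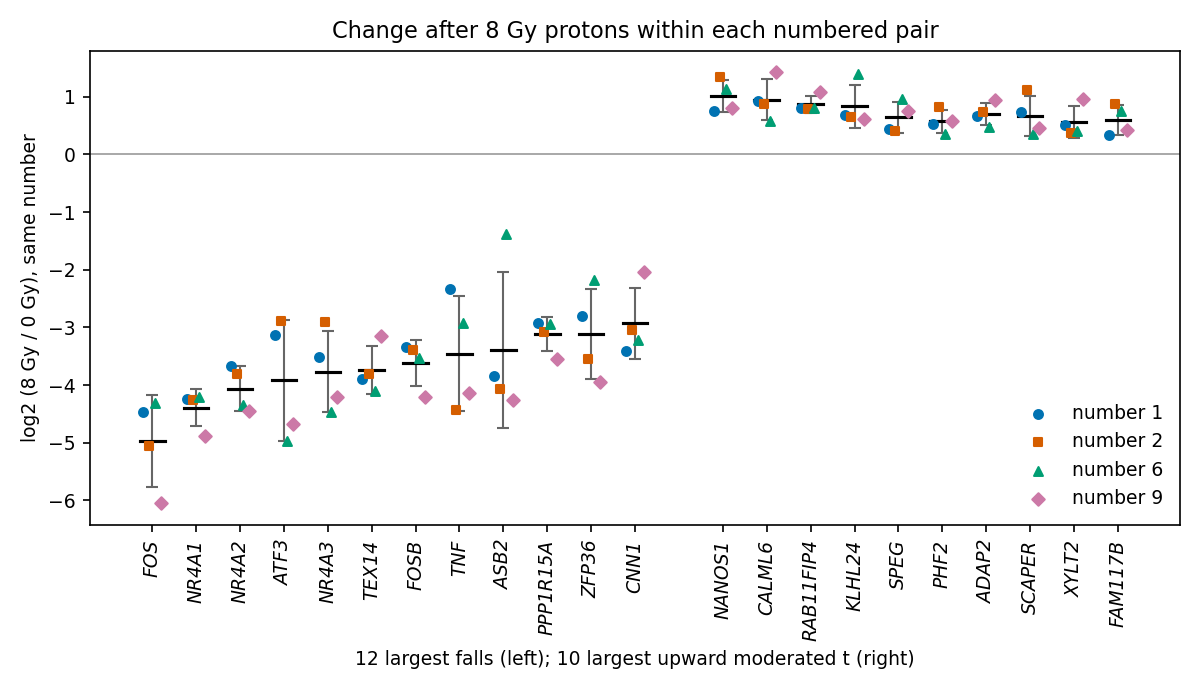
Log2 ratio of 8 Gy over 0 Gy within each number for the 12 largest falls and for the 10 genes with the largest upward moderated t. Symbols are the 4 numbers, black bars their mean and whiskers 1 SD. All 4 numbers lie below 0 for each of the 12 falls, and values of TEX14, TNF, ASB2 and CNN1 are measured values whose irradiated arrays were not well above background.

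Of the 31 immediate early genes 8 passed the test, all lower, or 21 adjusted over the list alone, and IER5 was the 1 member with a difference above 0 (0.18). The paired fit called 24 members lower and 0 higher, or 27 lower adjusted over the list alone. The median change was -1.52 on the log2 scale, and within the slides of numbers 1, 2, 6 and 9 it was -1.10, -1.38, -1.56 and -1.83. Camera gave an adjusted p of 7.26e-43 with its preset correlation and an adjusted p = 0.0867 with an estimated correlation, or 0.313 with the block. With the block, fry called 3 of the 21 lists. These were this list (adjusted p = 0.0177), the mesenchymal list (0.0177) and the NF-kB list (0.0335). Of 18 cytokine and feedback genes of the NF-kB pathway, 2 were lower, TNF and the pathway inhibitor TNFAIP3 (measured log2 change -2.43 ± 0.81, adjusted p = 0.0413, above background on 1 of the 4 irradiated arrays, -0.24 with an adjusted p = 0.991 under normexp, -0.92 and 0.827 with repaired backgrounds, 0.0551 under quantile normalization and 0.085 with no filter on dim probes), or 6 adjusted over the list alone. The paired fit called 9 of the 18 lower, or 11 adjusted over the list alone, and 1 higher by that count. Among the 9, LIF was 2.02-fold lower (paired adjusted p = 0.00188, 0.0862 without the block) and BIRC3, an inhibitor of apoptosis, 2.45-fold lower (paired adjusted p = 0.00317). Their camera adjusted p was 1.53e-09, and the adjusted p = 0.308 with an estimated correlation. The list mean was -1.01, and -0.60 under normexp.

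Other stress response lists held single genes that passed the test or passed it only with pairs as blocks. Of 21 genes of the unfolded protein and integrated stress responses, 1 fell, PPP1R15A, or 2 adjusted over the list alone. In the paired fit 5 were lower, also by the list alone, including DDIT3 (4.42-fold, paired adjusted p = 6.21e-05, 0.055 without the block), SESN2 (1.98-fold) and DDIT4 (1.78-fold). The list's camera adjusted p was 0.00475, and its adjusted p = 0.626 with an estimated correlation; its median was -0.016 and its mean -0.36. Without the irradiated array of number 6 that call ended (adjusted p = 0.0999), but it held with both arrays of number 6 left out (0.0171). Of 15 heat shock genes none passed the unpaired test, with 1 lower adjusted over the list alone. In the paired fit 3 were lower, or 4 by the list alone: HSPA6 (29.4-fold, log2 change -4.88 ± 1.57, paired adjusted p = 0.000711, 0.0597 without the block), HSPA1A (3.11-fold, a probe that near-identical HSPA1B can share) and the co-chaperone DNAJB1 (1.6-fold). BAG3 had a difference of -0.48 ± 0.38 (paired adjusted p = 0.108), the list median was 0.043 while its mean was -0.41, and camera gave an adjusted p of 0.214. Of 18 NRF2 and oxidative stress genes, OSGIN1 (1.68-fold) and the heme oxygenase gene HMOX1 (1.82-fold) were lower in the paired fit, 2 also by the list alone, where the unpaired fit called 1. SRXN1 and SQSTM1 had paired adjusted p values of 0.109 and 0.11. That list's camera adjusted p was 0.122.

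CDKN1A, which codes for the cell cycle inhibitor p21, was 1.89-fold lower (log2 change -0.92 ± 0.15, paired adjusted p = 0.00255, 0.71 without the block), and the ubiquitin ligase gene MDM2 1.52-fold lower (-0.60 ± 0.20, paired adjusted p = 0.0261, 0.9 without). Under normexp without the block MDM2 turned to 0.26 (adjusted p = 0.951), and with repaired backgrounds it was -0.32 (0.96). Of 30 p53 target genes 0 passed the unpaired test, by the list alone too. In the paired fit 8 were lower and 0 higher, or 8 lower and 3 higher adjusted over the list alone. The 8 included the stress cytokine gene GDF15 (4.61-fold, -2.21 ± 0.47, and -1.18 under normexp), GADD45A (3.17-fold), the antiproliferative gene BTG2 (2.13-fold) and SESN2. The list's median was 0.033 and its mean -0.23, opposite in sign. Its camera adjusted p was 0.0572, or 0.0353 with the block, and the paired adjusted p = 0.489 with an estimated correlation. At the preset correlation without the block, the camera adjusted p was 0.0016 under normexp (0.00509 with repaired backgrounds). It was 0.0419 under median scaling and 0.0279 with no filter on dim probes. The list passed in 21 of 30 settings, most of them at the preset correlation. The list mean was -0.11 without the irradiated array of number 6 (camera adjusted p = 0.256) and -0.35 without the unirradiated one (0.0068). With both of these left out it was -0.24 (0.0131). Of 32 genes of double-strand break repair and checkpoints, DCLRE1C, which codes for the nuclease Artemis, was lower in the paired fit (1.69-fold, paired adjusted p = 0.0126, log2 change -0.76, and -0.44 under normexp), or 3 genes by the list alone. RNF168, RAD52 and RBBP8 had paired adjusted p values of 0.052, 0.056 and 0.122, and the list's camera adjusted p was 0.396.

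The median change of the 45 measured mitotic genes was -0.33 on the log2 scale, and it was -0.32, -0.18, -0.20 and -0.35 within the slides of numbers 1, 2, 6 and 9. Their mean of -0.34 became -0.11 without the irradiated array of number 6, -0.59 without the unirradiated array of number 6 and -0.22 without that of number 9. It was -0.37 with both arrays of number 6 left out. None of the 45 members passed the unpaired test over all genes and 4 were lower adjusted over the list alone. The paired fit called 9 lower and 0 higher, or 21 lower adjusted over the list alone. The mitotic kinase gene AURKA was 2.1-fold lower (log2 change -1.07 ± 0.084, paired adjusted p = 0.000956, 0.244 without the block), cyclin F (CCNF) 1.99-fold (log2 change -0.99, but -0.31 under normexp and -0.67 with repaired backgrounds), the centromeric histone gene CENPA 1.91-fold and the spindle gene FAM83D 1.72-fold. Camera gave an adjusted p of 7.42e-09, and an adjusted p = 0.626 with an estimated correlation, or 0.344 with the block. Of 37 genes of the G1/S transition and DNA replication, CCNE2, which codes for cyclin E2, was 1.53-fold higher in the paired fit (paired adjusted p = 0.0262) and was also the 1 gene called by the list alone. CCNE1, UHRF1 and MSH6 had differences of 0.50, 0.51 and 0.41 with paired adjusted p values of 0.0688, 0.0861 and 0.094. The list's camera adjusted p was 0.0133, upward, and its adjusted p = 0.555 with an estimated correlation; quantile normalization ended that call (adjusted p = 0.184), as did leaving out the unirradiated array of number 2 (0.121) or the irradiated array of number 1 (0.187) and normexp (0.349, or 0.0243 with repaired backgrounds). Of 22 histone genes, whose near-identical copies can share probes, 0 passed the unpaired test and 5 were lower in the paired fit, or 7 by the list alone. H2AC6 was 2.1-fold, H4C5 1.58-fold and H3C4 1.45-fold lower (under normexp the log2 changes of H2AC6 and H4C5 went from -1.07 and -0.66 to -0.50 and -0.43, and H3C4 from -0.54 to -1.09 in the value table), and H3C8 had a difference of -0.35 ± 0.12 (paired adjusted p = 0.109). Their camera adjusted p was 0.00475, and the adjusted p = 0.64 with an estimated correlation. Without the irradiated array of number 6 the call ended (adjusted p = 0.644) and the list mean turned from -0.27 to 0.088, and without the unirradiated array of number 2 the adjusted p was 0.0942 and the mean -0.097. The mean was -0.58 without the unirradiated array of number 6 and -0.51 without the irradiated array of number 2. Leaving out 1 array unbalances the groups by number, and number 6 was itself low for these genes (median difference from the other numbers -1.52). With both arrays of number 6 left out, the histone mean was -0.22 (camera adjusted p = 0.00116).

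**Figure D2:**
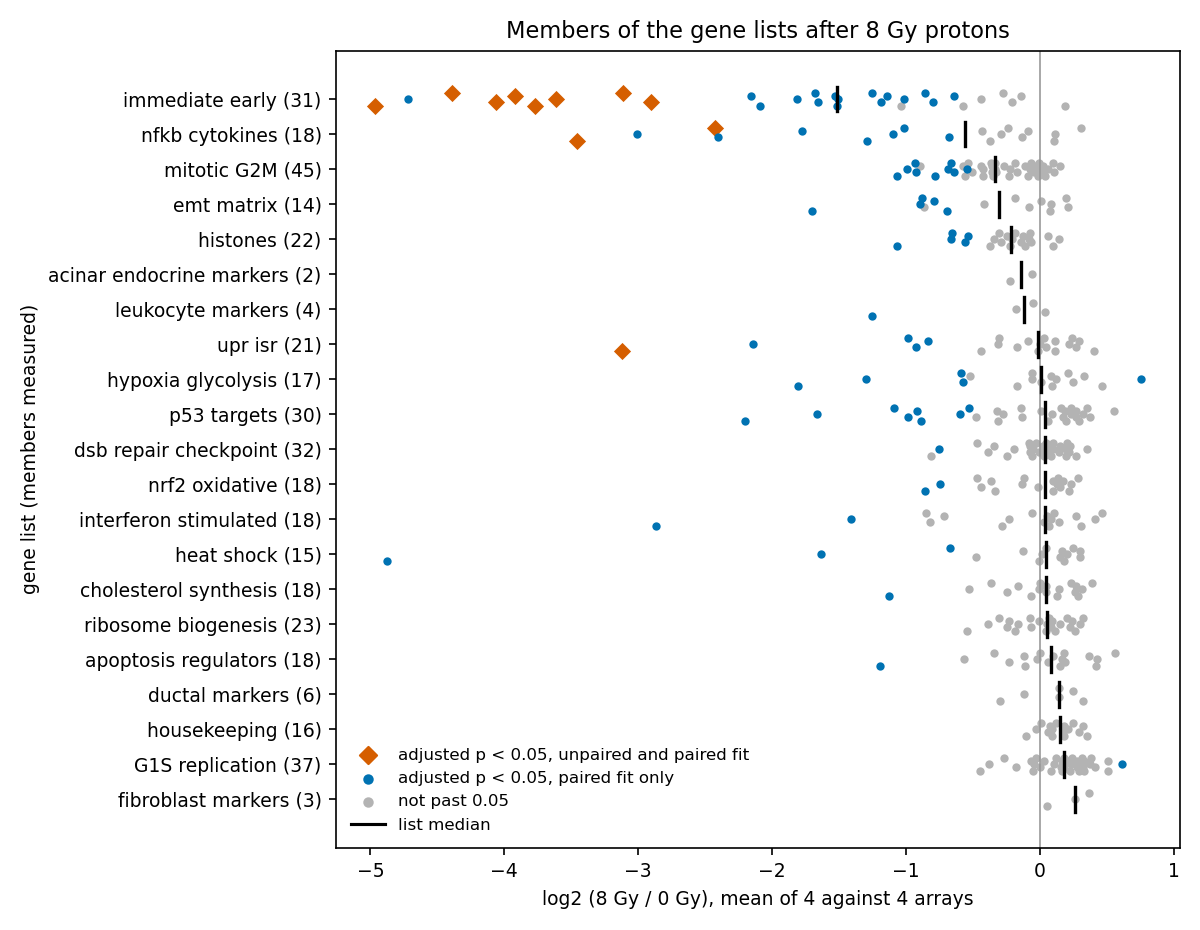
Log2 ratio of 8 Gy over 0 Gy for each measured member of the 21 gene lists, with list medians as black bars and the number of measured members in parentheses. Orange diamonds passed an adjusted p of 0.05 with and without pairs as blocks, blue points only with them, grey points in neither. Immediate early genes have the lowest median, -1.52, and housekeeping genes lie at 0.15 and, as a mean, at 0.14 or, under quantile normalization, -0.016.

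Of 14 genes of mesenchymal state and extracellular matrix, 5 were lower in the paired fit, the same number by the list alone, and 0 in the unpaired fit. They included the transcription factors SNAI1 (1.86-fold) and ZEB1 (1.73-fold, above background on 3 of the 4 irradiated arrays) and the matrix protein gene TGFBI (1.84-fold). Camera gave an adjusted p of 0.00475 and an adjusted p = 0.143 with an estimated correlation. Under normexp the list call ended (adjusted p = 0.129). The list mean went from -0.43 to 0.051, ZEB1 from -0.79 to 0.20 and SNAI1 from -0.89 to -0.59. With repaired backgrounds the list kept its call (adjusted p = 0.00477), with a mean of -0.23 and ZEB1 at -0.29. The list mean was -0.20 with no filter on dim probes and -0.19 without the irradiated array of number 6. With both arrays of number 6 left out it was -0.38. Of 17 hypoxia and glycolysis genes, 4 were lower in the paired fit, among them ADM (3.5-fold) and ANKRD37 (2.47-fold), and the mitophagy receptor gene BNIP3L was 1.69-fold higher (paired adjusted p = 0.0144). By the list alone 2 were lower without the block, and 5 lower and 2 higher with it. PFKFB3 had a difference of -0.52 ± 0.24 (paired adjusted p = 0.0539), other PFKFB3 probes ranged from -1.57 to 0.16, and the camera adjusted p was 0.122. Of 18 interferon-stimulated genes, OASL (7.31-fold, -2.87 ± 1.47) and IRF1 (2.66-fold, -1.41 ± 1.06) were lower in the paired fit, or 3 lower and 2 higher by the list alone. IFIT2 and ISG15 had paired adjusted p values of 0.12 and 0.0786, and the camera adjusted p was 0.122. The interferon list mean of -0.30 became -0.67 without the irradiated array of number 6 (camera adjusted p = 0.00326) and 0.10 without the unirradiated one. The list also passed without the unirradiated array of number 1 (0.00539) or 2 (0.0343). With both arrays of number 6 left out it did not (mean -0.28, adjusted p = 0.422).

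Of 18 genes of cholesterol synthesis and uptake, 1 was lower in the paired fit, or 2 genes lower and 1 higher by the list alone, where the unpaired fit called 1 lower. HMGCS1, CYP51A1 and DHCR7 had paired adjusted p values of 0.0624, 0.178 and 0.221, and the camera adjusted p was 0.815. Of 18 apoptosis regulators, PMAIP1, which codes for the BH3-only protein NOXA, was 2.28-fold lower (paired adjusted p = 0.0077), or 1 lower and 2 higher by the list alone, where the unpaired fit called 1 lower. BID and BAD had differences of 0.43 and 0.36 with paired adjusted p values of 0.0814 and 0.12, and camera gave 0.827. Of 23 ribosome biogenesis genes 0 passed either fit, by the list alone too. RRP12, POLR1E, WDR43 and NOP2 had differences of -0.39, -0.54, 0.26 and -0.31, and the camera adjusted p was 0.627. Housekeeping genes had 0 of 16 members past the threshold in either fit, with RPL13A, HPRT1, GUSB and RPLP0 at 0.35, 0.32, 0.29 and 0.18 and a camera adjusted p of 0.122. Their mean was 0.14, and -0.016 under quantile normalization. With that normalization the heat shock, NRF2, p53, hypoxia and ribosome biogenesis lists also passed camera downward, with an adjusted p of 0.00543, 0.00616, 0.0175, 0.0296 and 0.0475. These values rest on the preset correlation: with an estimated correlation, in the 75th percentile scaling, the same lists had an adjusted p = 0.744, 0.391, 0.634, 0.626 and 0.82.

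Markers of other pancreatic cell types were mostly not measured above background. Of 10 markers each, 4 leukocyte, 3 fibroblast, 2 acinar or endocrine and 6 ductal ones entered the test. The leukocyte integrin gene ITGAM, above background on 3 unirradiated and 1 irradiated arrays, was lower in the paired fit (measured log2 change -1.25, paired adjusted p = 0.00341) and turned to 0.49 under normexp without the block (adjusted p = 0.87), or -0.23 with repaired backgrounds (0.96). It was the 1 member called by the list alone in each fit, while CD3E, CD68 and CD14 had differences of -0.18, -0.055 and 0.039. That list's camera adjusted p was 0.0339, or 0.112 with the block, and the adjusted p = 0.308 with an estimated correlation. Its mean turned from -0.36 to 0.39 under normexp (adjusted p = 0.427) but was -0.056 with repaired backgrounds (0.304), and the call also ended without the unirradiated array of number 2 (0.0909) or the irradiated array of number 1 (0.0798) or 6 (0.241). No member of the other lists passed either fit, by the list alone too. PDGFRA, THY1 and COL1A2 had differences of 0.37, 0.26 and 0.052 (camera adjusted p = 0.301), CEL and CHGA differences of -0.23 and -0.062 (0.49), and MUC1, SOX9, CA2 and KRT8 differences of 0.32, -0.12, -0.30 and 0.14 (0.827).

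No gene passed the unpaired limma test upward. The 10 genes with the largest upward moderated t were NANOS1 (1.01 ± 0.28 on the log2 scale), CALML6 (0.95 ± 0.35), RAB11FIP4 (0.87 ± 0.14), KLHL24 (0.83 ± 0.38), ADAP2 (0.70 ± 0.19), SCAPER (0.66 ± 0.35), SPEG (0.64 ± 0.27), FAM117B (0.60 ± 0.26), PHF2 (0.57 ± 0.20) and XYLT2 (0.56 ± 0.27), each higher in 4 of 4 pairs. Their adjusted p values ran from 0.264 to 0.465, and from 0.00324 to 0.0487 in the paired fit. Another KLHL24 probe had a difference of 0.17. As means of their probes KLHL24 and PHF2 were at 0.50 and 0.34, in the value table at 0.075 and 0.25, and XYLT2 was at 0.35 under normexp. The median of all genes was 0.081 in this scaling and 0.17 when arrays were scaled to their median, so changes of this size stand partly on the scaling.

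The second comparison asks how the 4 numbers of the titles differ from each other in either group. Number 6 stood apart. The kallikrein protease gene KLK7 was at least 77.1-fold lower in it than in the mean of the other numbers, as were the neuronal cytoskeleton gene MAP2 (at least 107-fold), HPDL (at least 152-fold), PDZK1IP1 (at least 178-fold), SIPA1L2 (at least 32-fold) and IL1RAPL1 (at least 30.4-fold), none of which was well above background on either array of number 6. The interferon-induced gene IFI27 was 96.5-fold higher in number 6 and the annexin gene ANXA10 73.0-fold higher. Each was well above background on 5 arrays of the other numbers but not on all, so these folds rest in part on a value at background. These are the 8 genes with the largest F among those with a symbol. Limma's moderated F test called 9663 of 17622 genes between the 4 numbers and 2945 when number 6 was left out. In number 6, 498 genes lay more than 4-fold from the mean of the other numbers, 189 higher and 309 lower, against 65, 76 and 97 genes in numbers 9, 1 and 2. Number and slide are the same split, so a number and its slide cannot be told apart. Numbers 1 and 6 were also each scanned on a day of their own, and numbers 2 and 9 on the same day.

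**Figure D3:**
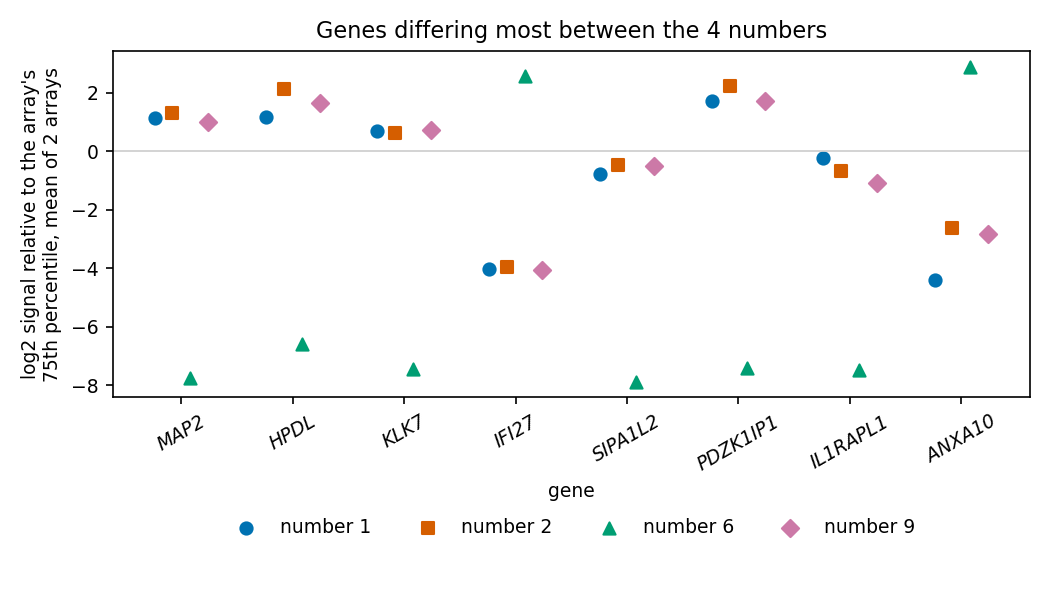
Log2 signal relative to the array's 75th percentile for the 8 genes with the largest F between numbers, as the mean of the 2 arrays of each number. Number 6 lies 6.19 or more above the mean of the other numbers for ANXA10 and IFI27 and below it for the other 6 genes.

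**Figure D4:**
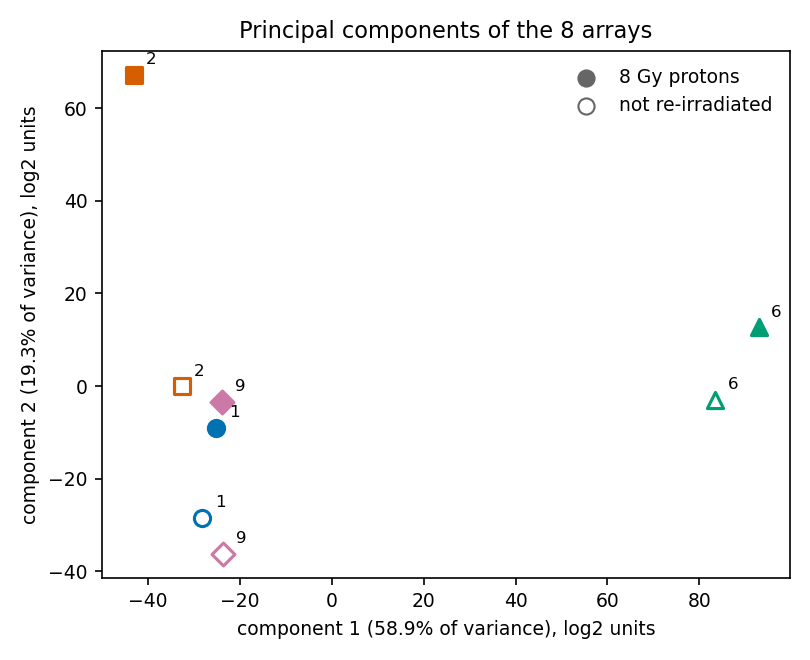
First 2 principal components of the 8 arrays over the genes tested, with filled symbols for 8 Gy and open symbols for no re-irradiation. Component 1 (58.9% of the variance) parts number 6 from the other numbers, and component 2 (19.3%) has the irradiated array of number 2 at its upper end.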

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

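The tests of swapped labels, of a mixture of cells and of MAPK output were chosen after the results they bear on had been seen, and the other tests before. In groups of 4 samples, a value was singled out where its gap to the next sample, divided by the group's range, exceeded Dixon's 95% critical value for 4 samples, which chance gives in about 1 of 20 groups, or 13 of the 260 tested. It happened in 37, and in 32 of these the sample was number 6; 14 of the 32 are genes picked because numbers differ.

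In the unirradiated group the gap over range set number 6 apart for ASB2 (0.952), GDF15 (0.83), BTG2 (0.879), CCNF (0.84), H3C4 (0.903), CD14 (0.898), MUC1 (0.876), MAP2 (0.971), HPDL (0.901), KLK7 (0.986), SIPA1L2 (0.955), PDZK1IP1 (0.951) and IL1RAPL1 (0.882), all low, for IFI27 (0.98), high, and for the means of the mitotic (0.888) and heat shock (0.984) lists, both low. Number 1 was apart for BIRC3 (0.833, low) and CD3E (0.923, high), and number 9 for WDR43 (0.938, low), CEL (0.972, high) and the cholesterol list (0.846, low). After protons number 6 was apart for RAB11FIP4 (0.893), OASL (0.833), ISG15 (0.895) and IFI27 (0.982), high, for DNAJB1 (0.863), GUSB (0.87), MDM2 (0.93), MAP2 (0.965), HPDL (0.882), KLK7 (0.982), SIPA1L2 (0.953), PDZK1IP1 (0.927) and IL1RAPL1 (0.877), low, for the mitotic list (0.884, low) and the interferon list (0.936, high), and for the share of probes above background (0.833, high).

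The first pattern is the low level of immediate early and stress genes in the irradiated samples. In the unpaired fit 1 of the 35 splits of the 8 arrays into 4 and 4, the real one, called as many as 28 genes, and the highest other split called 1. Of these 35, 27 leave at least 1 pair together and so hold differences between numbers. The real split is 1 of the 8 that part all 4 pairs. Among these the paired fit called 839 genes in the real one and 0 in the highest other, the unpaired fit 28 and 0, and 8 splits are too few for a share under 0.05. Labels swapped in some pairs would turn the fold changes of those pairs, but the lowest correlation between 2 pairs across genes was 0.38. A single-probe effect of the slide position, which is confounded with dose, is argued against by other probes of the genes lower in the paired fit, of which 97.9% were lower too, against 53.5% of other probes over all genes. Still open are a position effect on whole samples and labels swapped in all 4 pairs. That swap was tested on the mitotic genes, on the premise that a G2 block after irradiation lowers them. In the paired fit 9 were lower and 0 higher. The rotation test fry gave a paired p = 0.00984 (adjusted 0.0517), and camera with an estimated correlation a paired p = 0.0655 (unpaired 0.254). In the same fit 8 p53 targets and 24 immediate early genes were lower and 0 higher, and 651 of the 839 calls were lower. Fry does not ask whether a list falls more than other genes, so the mitotic genes do not decide the swap. Also open, and untested, is an effect of the protons or handling that differed between the groups before harvest. Immediate early genes switch on within minutes of a stimulus, so handling bears on them, and the titles give no time for the unirradiated samples.

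For the gene lists, 5 of the 35 splits called as many lists as the real one (8), and the highest other called 10, so with the preset correlation chance cannot be excluded for the number of lists. The 27 splits that leave a pair together count here too. Among the 8 that part all pairs the highest other called 6, and 8 are too few for a share under 0.05.

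The second pattern is number 6, whose arrays correlated with the other 6 at 0.933 to 0.952 across genes. An effect of its slide on single probes is argued against, since 97.5% of other probes of the genes more than 4-fold apart differed the same way. For a mixture with other cells, the 20 largest falls in number 6 had a median of -8.20 on the log2 scale, but the genes were picked for their falls and 18 of them were not above background on both arrays of number 6, so the value excludes nothing. What stays open is whether number 6 is a culture that diverged, a mixture, another line or a swap with a sample outside the series. An effect of slide or scan day on whole samples stays open too, since number 6 had a slide and a scan day of its own. The labels give the numbers no meaning, and lower output of the MAPK pathway (percentile 20.1) stays undecided.

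The third pattern is the irradiated array of number 2, at the end of component 2. Weak signal of that array, the dimmest of the 8, would add spread among dim genes only. For each pair, the SD across genes of its fold changes minus the mean of the other pairs was taken. Among the brightest genes, however, this SD was 0.36 for number 2, which was 1.6 times the mean SD of the other numbers. Shorter RNA would favour 3′ probes, and the median of the 3′ minus the 5′ probe rose by 0.35 on the log2 scale in that pair, above 0.14, 0.035 and 0.012 in numbers 9, 6 and 1. Taken per array, against each gene's mean over the arrays, this median was 0.40 on the irradiated array of number 2 and 0.052 on its unirradiated partner. The unirradiated arrays of numbers 1, 6 and 9 lay at -0.081, -0.10 and -0.15, so number 2 was the highest without protons too. The irradiated array of number 9 lay at -0.017. A lower RNA integrity in that sample would give such values, and a change in transcript processing after protons is not excluded. The integrity itself was not among the data used here.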

How the results depend on the processing

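The settings that leave out both arrays of a number, that combine the replicate block with another choice, or that repair odd local backgrounds were chosen after the data had been seen. Unless a cause is named, the cause was not tested. The 28 genes lower after protons, with 0 higher, became 8, all lower, under normexp, 16 with no filter on dim probes (more genes tested) and 16 with the filter on all 8 arrays. They became 14 under normexp with repaired backgrounds, 1 without both arrays of number 2, and 120 (118 lower, 2 higher) without those of number 6. On the irradiated array of number 6, 6 spots had a local background over 10 times the array median, up to 46118, and normexp fitted a background mean of -869 there against -9.61 after repair. With scan day as a block 205 genes passed, 196 lower and 9 higher. Leaving out 1 array gave 3 to 63 changed genes, 3 to 62 lower and 0 to 1 higher. Quantile normalization, median scaling, the mean of a gene's probes, every probe, a trended spread and the value table gave 22 to 32, all lower. Of the 28, the number kept was 8 under normexp, 13 with no filter, 16 on all 8 arrays or in the value table, which holds 18 of them, 20 under quantile normalization and 28 with the block.

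The replicate block, pairing samples by number, gave 839 genes, 651 lower and 188 higher. With it, normexp gave 7, all lower, normexp with repaired backgrounds 2039 (888 lower, 1151 higher), median scaling 1485 (658 lower, 827 higher), quantile normalization 627 (459 lower, 168 higher) and no filter 68, all lower. Left out in turn, number 1 gave 754 (635 lower, 119 higher), number 2 gave 424 (394 lower, 30 higher), number 6 gave 1171 (940 lower, 231 higher) and number 9 gave 183 (177 lower, 6 higher). The share of higher genes was thus 22.4% in the paired fit, 55.7% under median scaling and 56.4% under normexp with repaired backgrounds. The median of all genes was 0.081, and -0.11 in the value table. Genes differing between numbers went from 9663 to 263 under normexp, 12372 under normexp with repaired backgrounds and 4155 with no filter, and from 2945 to 9042 with a number left out.

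A reversal is counted here where the sign changed and the result passed 0.05 in either fit, a limit set after a first count of every sign change; among results past it in neither, the sign changed in 43 gene and 20 list comparisons. Under normexp CNN1 went to 0.042, the G1/S list, by camera's direction, to a mean of 0.079 and the leukocyte list to 0.39, and both lists also did so with the block and normexp (0.079 and 0.39). With repaired backgrounds these signs did not turn: CNN1 was at -0.72, the G1/S list at 0.16 and upward, the leukocyte list at -0.056 and the mesenchymal list at -0.23. Lists are counted by camera's direction, and the mean of the mesenchymal list also changed sign under normexp (0.051), as did that of the histone list without the irradiated array of number 6 (0.088). The histone mean was -0.22 with both arrays of number 6 left out. Of 1745 comparisons of named genes with a planned setting, 1609 kept their side of the threshold, 63 lost the call, 72 gained it and 1 reversed; of 377 for lists the counts were 314, 28, 33 and 2. The immediate early list passed in 29 of 30 settings, with means of -2.10 to -1.54, but most of these settings share camera's preset correlation. With an estimated correlation it failed (camera adjusted p = 0.0867). It also failed with an estimated correlation and the block (0.313), which is not among the 30. Dim signal limits the falls to background, which are bounds.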

Other observations

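The MAPK test and the choice of the genes named here that the reported comparisons do not name came after the values were seen. The moderated F test between numbers called 9663 of all 17622 genes, and no set test of number 6 was run. Of 18 interferon-stimulated genes, 14 were higher in number 6 than in the mean of the other numbers and 2 lower among those called by the moderated F test between numbers, with a median difference of 1.32 on the log2 scale. OASL was 25.7-fold higher, ISG15 8.01-fold and MX1 2.52-fold. All 6 measured ductal markers were lower and called, with KRT19, a keratin of ductal epithelium, 21.4-fold and MUC1 5.51-fold lower. Mitotic genes were lower in 40 of 45 members called and higher in 0, with a median of -0.97, and 19 of 22 histone genes were lower and 1 higher.

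The kallikrein gene KLK6 was 292-fold lower in number 6 and the chemokine gene CXCL2 17.3-fold lower. The laminin gene LAMB1 was 55.8-fold higher and SERPINF1, an antiangiogenic factor, 42.3-fold higher.

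DUSP6, a phosphatase that ERK signalling induces, was 79.7-fold lower in number 6. Lower output of the MAPK pathway may be behind this, and it was tested on 10 known transcriptional targets of the pathway. The first version of the test held all 10, DUSP6 included, and their median difference of -0.50 lay at percentile 3.14 among 10000 random lists of the same size and level. Since DUSP6 had prompted the test, it was then left out, and the bounds for reading the result were changed after both outcomes had been seen. The 9 other genes had a median of -0.30, at percentile 20.1, with 4 of them lower and 1 higher by the moderated F test between numbers. EPHA2 was 3.40-fold, EPHA4 1.71-fold and PHLDA1 1.64-fold lower, and CCND1 was higher by 0.58 on the log2 scale. The outcome thus turns on the gene that prompted it, and lower MAPK output stays undecided.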
